A study of Mus musculus with 7 samples.

How the data were processed

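Polyadenylated RNA from 5 mouse B-ALL samples was sequenced. The labels describe the 3 Pax5-Etv6 libraries as strand-specific with a named cDNA synthesis kit and leave this field blank for the 2 control libraries. The deposited values are TPM, with 1 table per library, and each table sums to 1000000 over its 24726 gene entries. Per the submitters' processing notes, genome build mm9, HTSeq 0.5.3 and DESeq2 1.4.1 were used in the study, with no role given to each. The aligner, the gene models and their lengths are not given in the sources used here. Some deposited gene names carry tags whose meaning is not given in the sources used here; 3203 entries have one that reads as overlap and 474 one that reads as duplicate, and genes named in the text say where they carry the former. The 2 Pax5-Etv6 chromatin immunoprecipitation samples of the series were not analysed here.

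Whole reads underlie the TPM values. In all 16538 entries above 0 in at least 2 libraries (100%), the values were whole-number multiples of what 1 read is worth, within a tolerance of 1e-06 and with a largest deviation of 9.3e-10; with wrong constants 1.63% passed. The recovered totals ran from 20110795 to 50994959 reads per library. Recovered reads are the smallest whole numbers that give the values of an entry, so they and the totals are lower bounds. Recovered reads set the floor of 3 reads per library for a gene at 0 and served for counting intervals (95%, Wilson), which cover counting error only, since copies made by PCR are not independent molecules.

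The 5 libraries were grouped by genotype, 3 Pax5-Etv6 B-ALL against 2 control B-ALL, with replicates numbered in accession order. Genes with at least 1 TPM in at least 2 of the 5 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, no covariates, 3 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Within-group Pearson correlations of log2(TPM + 1) over genes were 0.955 to 0.978 and between-group ones 0.772 to 0.846. The first principal component, with 80.2% of the variance, separated the groups, and the second, with 10.4%, set Pax5-Etv6 replicate 1 (49.9) apart from replicates 2 (-23.1) and 3 (-23.2).

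The gene lists (41, holding 1017 symbols of which 1004 matched an entry), the tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from 2 alternatives chosen after seeing the data: voom (limma) on the recovered reads, and leaving out genes with an overlap or duplicate tag. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 39 lists, and again with an estimated correlation and with fry, whose p tests whether the genes of a list move one way on balance. Counts adjusted over the list alone equal the counts over all genes wherever no other count is given. Named genes were those of the genotypes, the 12 largest rises and 12 largest falls among called genes with a mean of at least 10 TPM in the higher group and no overlap between groups (leaving out unnamed or predicted genes and antigen-receptor segments, although 1 entry without a gene name remained), and up to 2 called members per list and direction. Igll1, Vpreb1, Erg, Rag1, Ms4a1, Klf2, Cd79b, Zap70, Pim1, Jak3, Tap1, Npm1, Pgk1, Slc7a5, Psat1, Notch1, Fcer1g, Nfkbia, Apoe and Cdkn2c were added after their values were seen, where the rule did not already name them.

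The other alternatives were pseudocounts of 0.1 and 5 TPM, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without the 50 highest and the mitochondrially encoded genes, no trend, robust empirical Bayes, and leaving out each library in turn. The fit was tested on simulated data with 200 of 11805 genes changed for this comparison: 10% of 2-fold and 60% of 4-fold changes were recovered, 4 of 74 calls were false, none of 40 unchanged lists was called and the list with a shift was called. Simulated genes varied independently of one another, so the list result does not test the effect of correlation between genes. The simulation also changed far fewer genes than the 6099 called in the data.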

Results

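RNA was sequenced from 5 mouse B-cell acute lymphoblastic leukaemias (B-ALL), all on the C57BL/6 background. In 3 of them, called Pax5-Etv6 B-ALL here, 1 Pax5 allele carries the Pax5-Etv6 fusion gene and 1 copy of the Cdkn2a-Cdkn2b locus is lost; the labels give whole lymph node used directly from the animal. The remaining 2, called control B-ALL, lack Trp53, carry an activated Nras allele and a retroviral Myc, and came from whole bone marrow after a short culture. Pax5 is the transcription factor that commits cells to the B lineage, and Etv6 is an ETS-family repressor. The comparison addresses which genes set leukaemias with the fusion apart from a B-ALL of another origin. Reads recovered from the deposited TPM values, as lower bounds, numbered 23286263, 20110795 and 30103488 for Pax5-Etv6 B-ALL replicates 1, 2 and 3, and 50994959 and 28740630 for control B-ALL replicates 1 and 2. Tissue, culture and cDNA protocol follow the groups, so each difference below is between these 2 kinds of sample as a whole. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples.

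The genes named in the genotypes were read first, as a check on the labels. Trp53, the tumour suppressor deleted in the control leukaemias, had 477 ± 19.8 TPM (SD, n = 3) in Pax5-Etv6 B-ALL and 15.9 ± 6.52 TPM (SD, n = 2) in control B-ALL (log2 fold change 4.88 ± 0.24 SE, limma adjusted p = 0.00037). All means below are given with the SD over the same 3 and 2 libraries, and fold changes with the SE on the log2(TPM + 1) scale, which understates the change of low genes. Myc, supplied by retrovirus in the control leukaemias, stood at 338 ± 50.7 against 1820 ± 389 TPM (-2.42 ± 0.20, adjusted p = 0.000608). Cdkn2a, which encodes the p16Ink4a and p19Arf inhibitors, stood at 28.8 ± 21.0 against 492 ± 93.3 TPM (-4.25 ± 0.51, adjusted p = 0.00143). Its neighbour Cdkn2b was low in all libraries, at 0.0663, 7.03 and 0 TPM against 1.73 and 3.11 TPM (-0.71 ± 0.92, adjusted p = 0.542). Etv6 was 3.20-fold higher in Pax5-Etv6 B-ALL, at 39.0 ± 2.77 against 12.2 ± 0.171 TPM (1.60 ± 0.19, adjusted p = 0.00132). Pax5 stood at 220 ± 26.6 and 226 ± 36.5 TPM (-0.03 ± 0.17, adjusted p = 0.882), and Nras at 57.4 ± 2.46 and 62.7 ± 1.89 TPM (-0.13 ± 0.15, adjusted p = 0.494). These values are per gene, so reads of the fusion transcript cannot be separated from those of the intact Pax5 and Etv6 alleles.

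**Figure D1:**
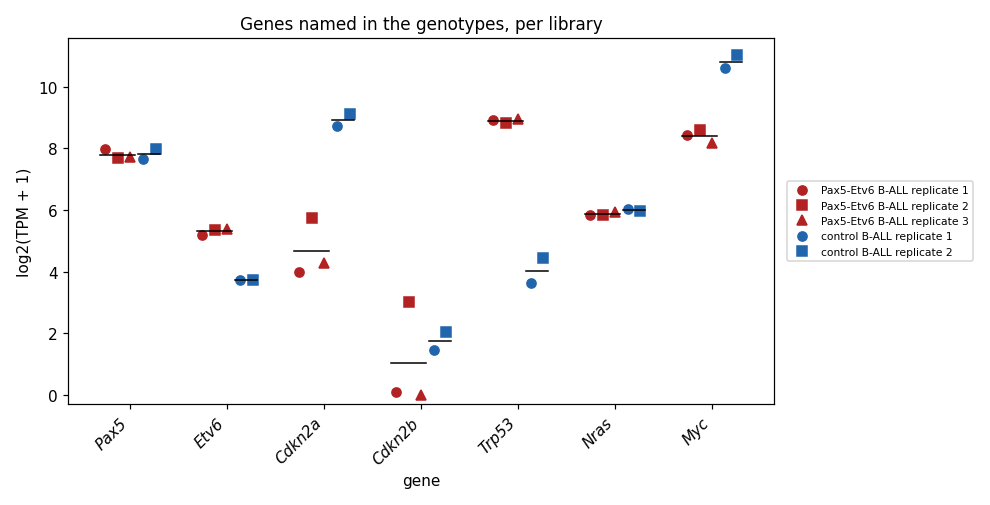
Expression of the 7 genes named in the genotypes, as log2(TPM + 1) on the vertical axis, with a point for each library and a bar at each group's mean (3 Pax5-Etv6 and 2 control libraries). Trp53 and Etv6 lay higher, and Cdkn2a and Myc lower, in all 3 Pax5-Etv6 libraries than in both controls.

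Pax5-Etv6 B-ALL differed from control B-ALL in the expression of 6099 of 11805 tested genes. Components of the pre-B-cell receptor, genes of cytokine and JAK-STAT signalling and genes induced by interferons were higher, led by Igll1, Cish and Gbp7 (each list at adjusted p = 0.642 with an estimated correlation, and so not called; fry did not call the type I interferon list, adjusted p = 0.0514). Ribosome biogenesis and MYC target genes and genes of the ATF4 amino-acid response were lower, led by Hspd1 and Asns (adjusted p = 0.398 and 0.642 with an estimated correlation). Markers of macrophages, neutrophils and stromal cells were also higher in Pax5-Etv6 B-ALL (adjusted p = 0.642, 0.642 and 0.682 with an estimated correlation), although fry called none of these 3 lists (adjusted p = 0.0849, 0.0634 and 0.194). Of 11805 genes tested with limma, 2588 rose and 3511 fell at an adjusted p under 0.05, and 1823 and 2505 of these had a log2 fold change of at least 1 in size. In all 6099 called genes the 3 Pax5-Etv6 libraries lay on 1 side of both controls. Such a separation was seen in 8528 genes (72.2%), against 20% by chance. Leaving out control B-ALL replicate 1 left 1410 genes higher and 1954 lower.

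B-lineage genes moved in both directions, with the surrogate light chain among the genes that rose most. Of 32 pre-B-cell receptor components and signalling genes, 19 rose, 3 fell and 10 were not called (median log2 fold change 0.92, camera adjusted p = 0.00204; adjusted p = 0.642 with an estimated correlation). Igll1, the lambda5 part of the surrogate light chain, stood at 1209 ± 871 against 17.1 ± 9.57 TPM (5.65 ± 0.96, adjusted p = 0.00438), and its partner Vpreb2 at 187 ± 31.0 against 4.32 ± 2.61 TPM (5.23 ± 0.33, adjusted p = 0.000391). The signalling chain Cd79b rose by a log2 fold change of 2.01 ± 0.24 (adjusted p = 0.00148), whereas the adaptor Blnk fell by 2.99 on the log2 scale (adjusted p = 0.000608) and the kinase Btk fell by 1.43 (adjusted p = 0.00112). Of 23 early B-cell genes, 11 rose, 5 fell and 7 were not called (median 1.16, adjusted p = 0.041; adjusted p = 0.687 with an estimated correlation). This call was lost without Pax5-Etv6 B-ALL replicate 2 (adjusted p = 0.0557) and without control B-ALL replicate 2 (adjusted p = 0.0996), within a range of 0.00701 to 0.0996 over all settings that kept the preset correlation. It was also lost under median-of-ratios scaling (0.0662), quantile normalization (0.085), rescaling without the highest genes (0.0558), no filter (0.0513), no trend (0.0562) and voom (0.0903). Enpep, the pre-B-cell surface peptidase BP-1, fell by 5.63 (adjusted p = 0.000511), to 0.140 ± 0.109 from 61.3 ± 37.8 TPM.

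Replicate 1 of Pax5-Etv6 B-ALL stood apart from the other two libraries of its group within these B-lineage genes. It was lowest of the 3 in 21 of 23 early B-cell genes and highest of the 3 in 15 of 19 mature B-cell genes and 10 of 11 genes of MHC class II presentation. Erg, an ETS-family factor of early progenitors, had 3.17, 75.4 and 106 TPM in replicates 1, 2 and 3 and at most 0.282 TPM in the controls. Its call (4.84 ± 1.34, adjusted p = 0.0235) was lost without control B-ALL replicate 1 (adjusted p = 0.124) or 2 (adjusted p = 0.118), within a range of 0.000168 to 0.152, and also with a pseudocount of 5 TPM (0.0565), no filter (0.0641) and voom (0.152). Vpreb1 had 98.2, 1173 and 1079 TPM against 95.6 and 15.4 TPM. Its call (3.65 ± 1.23, adjusted p = 0.0452) was lost without control B-ALL replicate 2 (adjusted p = 0.264) or 1 (0.0763) and without Pax5-Etv6 B-ALL replicate 2 (0.0798) or 3 (0.101), within a range of 0.00289 to 0.264. It was also lost with a pseudocount of 5 TPM (0.051), no filter (0.104), no trend (0.0626) and voom (0.0793). Rag1, of the recombinase, had 12.2, 124 and 180 TPM and was not called (adjusted p = 0.261). Of the 19 mature B-cell genes, 4 rose, none fell and 15 were not called (median 0.07, adjusted p = 0.184). The largest rise was in Cxcr5, the receptor that draws B cells to follicles (5.47 ± 0.41, adjusted p = 0.000508). Of 11 MHC class II genes 3 rose and 8 were not called (median 0.53, adjusted p = 0.134; 2 rose when adjusted over the list alone). H2-Oa, whose deposited name carries an overlap tag, stood at 3.40 ± 0.55 (adjusted p = 0.00366). Of 11 plasma-cell genes 6 rose, 4 fell and 1 was not called (median 0.46, adjusted p = 0.365). The plasma-cell regulator Xbp1 was higher (2.19 ± 0.32, adjusted p = 0.00266) and Slamf7 lower (-1.69 ± 0.21, adjusted p = 0.00173).

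Genes that Pax5 is known to repress were higher as a group, and genes it is known to activate were not called as a group. Macrophage and T-cell markers were higher in the same libraries, as given below, and Fcer1g is in the macrophage list too (adjusted p = 0.00576, but 0.061, the highest of a range from 0.000431, without control B-ALL replicate 1). Of 15 Pax5-repressed genes, 9 rose, 1 fell and 5 were not called (median 1.97, adjusted p = 0.00799; adjusted p = 0.642 with an estimated correlation). Notch1, a receptor of T-cell commitment, stood at 60.6 ± 15.7 against 10.8 ± 4.29 TPM (2.40 ± 0.33, adjusted p = 0.00216). The plasma-cell regulator Prdm1 rose by 3.94 ± 0.88 (adjusted p = 0.0114), a call lost without control B-ALL replicate 1 (adjusted p = 0.0821) or 2 (adjusted p = 0.0673), within a range of 0.000265 to 0.0821, and also with voom (0.0598). The deposited names of Notch1 and Grap2, among others, carry an overlap tag, and without tagged genes the list's adjusted p was 0.064, the highest of a range that began at 0.00157. Fry did not call the list (adjusted p = 0.0514). Of 25 Pax5-activated genes, 9 rose, 5 fell and 11 were not called (median 0.30, adjusted p = 0.242). Vpreb3, which binds immunoglobulin chains during assembly, was higher (1.96 ± 0.27, adjusted p = 0.00218) and Blnk lower.

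Genes of cytokine signalling and of the interferon responses were higher in Pax5-Etv6 B-ALL. Of 32 cytokine receptor and JAK-STAT genes, 23 rose, 2 fell and 7 were not called (median 1.37, adjusted p = 1.90e-06; adjusted p = 0.642 with an estimated correlation), and 24 rose when adjusted over the list alone. Cish, a feedback inhibitor induced by STAT5, stood at 79.0 ± 35.1 against 0.0489 ± 0.0377 TPM (6.17 ± 0.37, adjusted p = 0.000391). The feedback inhibitor Socs3 rose by 4.89 ± 0.37 (adjusted p = 0.000512), the kinase Pim1 by 3.42 ± 0.31 (adjusted p = 0.000679) and the kinase Jak3, whose name carries an overlap tag, by 2.61 ± 0.24 (adjusted p = 0.000726). All 14 tested genes of the interferon-gamma response rose (median 2.57, adjusted p = 1.85e-07; adjusted p = 0.642 with an estimated correlation). Among them the guanylate-binding protein Gbp7 stood at 79.6 ± 42.5 against 0.138 ± 0.0713 TPM (6.03 ± 0.42, adjusted p = 0.000429), and the peptide transporter Tap1 at 343 ± 74.3 against 57.4 ± 21.4 TPM (2.59 ± 0.28, adjusted p = 0.00112). Of 26 genes of the type I interferon response, 20 rose, none fell and 6 were not called (median 2.13, adjusted p = 1.85e-07; adjusted p = 0.642 with an estimated correlation), and 22 rose when adjusted over the list alone. Rtp4 and Oas1a led with 4.61 ± 0.66 (adjusted p = 0.00251) and 4.23 ± 0.47 (adjusted p = 0.00117). Macrophage and neutrophil markers were higher in the same libraries, as given below.

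Of 17 NF-kappaB target genes, 8 rose, none fell and 9 were not called (median 0.82, adjusted p = 0.00548; adjusted p = 0.642 with an estimated correlation), and 9 rose when adjusted over the list alone. The inhibitors Nfkbia and Nfkbie were among them, at 1.56 ± 0.21 (adjusted p = 0.00206) and 2.47 ± 0.34 (adjusted p = 0.00225). Of 20 immediate-early genes, 9 rose, 2 fell and 9 were not called (median 1.05, adjusted p = 0.0183; adjusted p = 0.682 with an estimated correlation). The AP-1 factor Fosb was higher (2.20 ± 0.29, adjusted p = 0.00188) and the orphan receptor Nr4a1 lower (-2.80 ± 0.24, adjusted p = 0.000608). That call was lost without Pax5-Etv6 B-ALL replicate 1 (adjusted p = 0.0562) and without control B-ALL replicate 1 (adjusted p = 0.0798), within a range of 0.00264 to 0.0798.

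Ribosome biogenesis and MYC target genes and genes of the ATF4 response were lower in Pax5-Etv6 B-ALL. Of 36 ribosome biogenesis and MYC target genes, 29 fell, 1 rose and 6 were not called (median -1.21, adjusted p = 1.85e-07; adjusted p = 0.398 with an estimated correlation). The mitochondrial chaperonin Hspd1 stood at 74.1 ± 10.6 against 713 ± 175 TPM (-3.24 ± 0.21, adjusted p = 0.000391), and the nucleolar protein Npm1 at 425 ± 84.1 against 1870 ± 843 TPM (-2.08 ± 0.31, adjusted p = 0.00284). The member that rose was the D-type cyclin Ccnd2, at 154 ± 101 against 4.54 ± 4.11 TPM (4.84 ± 0.65, adjusted p = 0.00207). Of 25 ATF4 amino-acid response genes, 17 fell, none rose and 8 were not called (median -1.08, adjusted p = 0.000752; adjusted p = 0.642 with an estimated correlation); adjusted over the list alone, 17 fell and 1 rose. Asns, which makes asparagine, had no read in the 3 Pax5-Etv6 libraries and 182 and 167 TPM in the controls. Against the TPM of 3 reads per library it was at least 1209-fold lower (limma adjusted p = 0.00037), and the list's median was -1.08 with Asns at that bound. The cDNA protocol follows the groups, and whether it or the counting of reads left Asns without a read was not tested. Psat1, of serine synthesis, fell by 1.73 (adjusted p = 0.000745) and the amino-acid transporter Slc7a5 fell by 1.72 (adjusted p = 0.000746).

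Of 14 heat-shock genes 7 fell, 1 rose and 6 were not called (median -0.58, adjusted p = 0.041; adjusted p = 0.642 with an estimated correlation). This call was lost without Pax5-Etv6 B-ALL replicate 3 (adjusted p = 0.0921, the highest of a range from 0.0146), under median-of-ratios scaling (0.0662), rescaling (0.0558) and no trend (0.0547), and without tagged genes (0.0503). Hsph1, an HSP110 chaperone, fell by 2.26 (adjusted p = 0.00142), and the co-chaperone Dnajb1 rose by 0.80 ± 0.19 (adjusted p = 0.0142). Of 22 cholesterol synthesis genes 9 fell, 1 rose and 12 were not called (median -0.80, adjusted p = 0.041; adjusted p = 0.687 with an estimated correlation). This call was lost without control B-ALL replicate 2 (adjusted p = 0.158, the highest of a range from 0.0152), with a filter of 5 TPM (0.058) and without tagged genes (0.0503). Insig1, a sensor of sterol levels, fell by 2.52 (adjusted p = 0.00291), and the methyl-sterol oxidase Sc4mol fell by 2.23 (adjusted p = 0.00452). Of 30 glycolysis and hypoxia genes 15 fell, 3 rose and 12 were not called (median -0.59, adjusted p = 0.108; 4 rose when adjusted over the list alone). The glycolytic kinase Pgk1 was lower (-1.74 ± 0.14, adjusted p = 0.000601) and Vegfa higher (2.24 ± 0.21, adjusted p = 0.000745). Of 39 oxidative phosphorylation genes 18 fell, 3 rose and 18 were not called (median -0.25, adjusted p = 0.244; 19 fell when adjusted over the list alone). Cytochrome c, Cycs, fell by 2.23 (adjusted p = 0.0031) and the ATP synthase subunit Atp5h rose by 1.20 ± 0.15 (adjusted p = 0.00166). Of 22 unfolded protein response genes 7 fell, 3 rose and 12 were not called (median -0.30, adjusted p = 0.437; 2 rose when adjusted over the list alone). The chaperone Hsp90b1 fell by 1.39 (adjusted p = 0.00211) and Herpud1, of protein degradation, rose by 1.42 ± 0.22 (adjusted p = 0.00307). Of 26 autophagy and lysosome genes 10 rose, 4 fell and 12 were not called (median 0.51, adjusted p = 0.0628). The autophagy receptor Sqstm1 was higher (1.95 ± 0.17, adjusted p = 0.000643). Cytosolic ribosomal protein genes split, with 23 of 76 higher, 11 lower and 42 not called (median 0.23, adjusted p = 0.0203; adjusted p = 0.694 with an estimated correlation). Rpl28 was highest (4.01 ± 0.26, adjusted p = 0.000391) and Rps25, whose name carries an overlap tag, lowest (-3.76 ± 0.15, adjusted p = 0.00037). Their call was lost without Pax5-Etv6 B-ALL replicate 1 (median 0.11, adjusted p = 0.211) and without control B-ALL replicate 2 (median 0.39, adjusted p = 0.0517), within a range of 0.00074 to 0.211. It was also lost under quantile normalization, where the median fell to 0.02 (adjusted p = 0.189), and under rescaling without the highest genes (0.0617). Reads of these genes can be shared with processed pseudogenes, so their values are uncertain. The limit may reach other genes with such copies. Gapdh, of the glycolysis list, had only 5.39, 8.67 and 5.32 TPM against 4.1 and 7.3 TPM. Values of Hspd1, Npm1, Cycs and Rps27l may carry the same limit, which was not tested.

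The cell-cycle, apoptosis and p53 lists were not called as groups. Of 40 proliferation genes 15 fell, 1 rose and 24 were not called (median -0.23, adjusted p = 0.134; 13 fell and 0 rose when adjusted over the list alone). Among the Pax5-Etv6 libraries, replicate 1 was lowest in 31 of the 40 and replicate 3 highest in 29. The mitotic cyclin Ccnb1 stood at 24.2 ± 0.785 against 142 ± 43.4 TPM (-2.47 ± 0.22, adjusted p = 0.000652). Of 12 cell-cycle inhibitors and senescence genes 6 rose, 2 fell and 4 were not called (median 0.57, adjusted p = 0.184). Cdkn1a, the p53-induced inhibitor p21, stood at 97.2 ± 36.3 against 1.97 ± 1.55 TPM (5.09 ± 0.43, adjusted p = 0.000602), and Cdkn2c at 196 ± 20.8 against 66.3 ± 8.31 TPM (1.55 ± 0.16, adjusted p = 0.00102). Of 27 p53 target genes 5 rose, 4 fell and 18 were not called (adjusted p = 0.861; 3 fell when adjusted over the list alone). Their median was -0.10 and their mean 0.08, camera gave the direction as up and fry as down, and the median was 0.01 after median-of-ratios scaling and 0.02 after quantile normalization. Among them Rps27l fell by 2.47 (adjusted p = 0.00183). Of 13 BCL2-family genes 5 rose, 1 fell and 7 were not called (median 0.17, adjusted p = 0.244). The survival factor Bcl2l1 was higher (3.10 ± 0.53, adjusted p = 0.00443) and Bcl2 lower (-1.26 ± 0.30, adjusted p = 0.0134).

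The RAS-MAPK, Notch, migration, progenitor and chromatin lists were not called as groups. Of 17 RAS-MAPK output genes 4 rose, 5 fell and 8 were not called (adjusted p = 0.511); the median was 0.54 and the mean 0.17, and camera gave the direction as up and fry as down. Ccnd1, the D-type cyclin that RAS signalling induces, stood at 3.95 ± 1.57 against 101 ± 41.4 TPM (-4.34 ± 0.37, adjusted p = 0.000608). Of 10 Notch pathway genes 5 rose, 2 fell and 3 were not called (median 0.98, adjusted p = 0.2). The Notch target Hes1 was higher (3.73 ± 0.41, adjusted p = 0.00113) and Rbpj, which carries the Notch signal to DNA, lower (-2.46 ± 0.33, adjusted p = 0.00207). Of 35 migration and adhesion genes 14 rose, 8 fell and 13 were not called (median 0.36, adjusted p = 0.125). The chemokine receptor Cxcr4 rose by 2.09 ± 0.22 (adjusted p = 0.00107), and the hyaluronan receptor Cd44 stood at 1.05 ± 0.394 against 146 ± 41.5 TPM (-6.15 ± 0.30, adjusted p = 0.00037). Of 5 haematopoietic progenitor genes 2 rose, 1 fell and 2 were not called (median 0.63, adjusted p = 0.244). Of 29 polycomb and chromatin regulators 9 rose, 6 fell and 14 were not called (median 0.12, adjusted p = 0.184; 10 rose when adjusted over the list alone). The histone deacetylase Hdac7, whose name carries an overlap tag, was higher (1.98 ± 0.25, adjusted p = 0.00176) and Suz12 lower (-1.04 ± 0.20, adjusted p = 0.0065).

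Markers of cell types other than B cells were higher in the Pax5-Etv6 libraries. Of 21 macrophage and monocyte markers 13 rose, 1 fell and 7 were not called (median 1.99, adjusted p = 0.000296; adjusted p = 0.642 with an estimated correlation), and 14 rose when adjusted over the list alone. Apoe stood at 334 ± 175 against 39.5 ± 18.7 TPM (3.01 ± 0.45, adjusted p = 0.00285). The member that fell was the integrin Itgam, at 3.46 ± 0.398 against 17.7 ± 3.56 TPM (-2.06 ± 0.27, limma adjusted p = 0.00187). Of 14 neutrophil markers 13 rose and 1 fell (median 2.47, or 2.29 with members at no read in the controls set to their bound; adjusted p = 0.000738; adjusted p = 0.642 with an estimated correlation). S100a9, an abundant neutrophil transcript, had 96.9, 9.66 and 53.9 TPM in replicates 1, 2 and 3 and at most 0.0917 TPM in the controls (5.21 ± 0.88, adjusted p = 0.00432). The neutrophil member that fell was Gfi1. Its call was lost without control B-ALL replicate 1 (log2 fold change -4.62) and without control B-ALL replicate 2 (-4.09). Of 17 stromal markers 12 rose, none fell and 5 were not called (median 2.88, adjusted p = 0.00108; adjusted p = 0.682 with an estimated correlation). The collagen Col3a1 had 14.4, 175 and 40.6 TPM against at most 0.279 TPM (5.39 ± 0.93, adjusted p = 0.00466). Of 11 T-cell markers 7 rose, none fell and 4 were not called (median 1.70, adjusted p = 0.00233; adjusted p = 0.642 with an estimated correlation), and 9 rose when adjusted over the list alone. The T-cell receptor kinase Lck, whose name carries an overlap tag, stood at 358 ± 155 against 9.35 ± 3.62 TPM (5.04 ± 0.45, adjusted p = 0.000651). Its partner Zap70 stood at 145 ± 83.2 against 18.0 ± 9.31 TPM (2.80 ± 0.62, adjusted p = 0.0112), a call lost without control B-ALL replicate 1 (adjusted p = 0.105, the highest of a range from 0.000897). The CD3 chains Cd3d, Cd3e and Cd3g summed to 1.03, 1.25 and 1.79 TPM in the 3 Pax5-Etv6 libraries.

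Erythroid markers rose in 4 of 6 cases with 2 not called (median 1.58, adjusted p = 0.00799; adjusted p = 0.642 with an estimated correlation), and in 5 when adjusted over the list alone. The carbonic anhydrase Car2 was among them, at 1742 ± 712 against 3.66 ± 1.69 TPM (8.49 ± 0.43, adjusted p = 0.00037), next to the haem-synthesis gene Alas2, whose name carries an overlap tag (4.24 ± 0.71, adjusted p = 0.00426). Of 12 endothelial markers 2 rose, 1 fell and 9 were not called (median 1.02, or 0.90 with members at no read in a group set to their bound; adjusted p = 0.041; adjusted p = 0.687 with an estimated correlation). That call was lost without Pax5-Etv6 B-ALL replicate 2 (adjusted p = 0.24) or 3 (0.154) and without control B-ALL replicate 1 (0.0945) or 2 (0.158), within a range of 0.00308 to 0.24. It was also lost with a pseudocount of 5 TPM (0.0564), under median-of-ratios scaling (0.0746), quantile normalization (0.0891) and rescaling (0.0597), and without tagged genes (0.0789). Of 11 adipocyte markers 3 rose, 1 fell and 7 were not called (median 1.11, adjusted p = 0.0222; adjusted p = 0.642 with an estimated correlation). Car3, abundant in fat, stood at 124 ± 56.7 against 1.55 ± 1.44 TPM (5.62 ± 0.54, adjusted p = 0.000795). The list's call was lost without Pax5-Etv6 B-ALL replicate 2 (adjusted p = 0.0676) or 3 (0.0517) and without control B-ALL replicate 1 (0.0571) or 2 (0.111), within a range of 0.00308 to 0.141 whose highest value came with a filter of 5 TPM. Its median moved to 2.27 without Pax5-Etv6 B-ALL replicate 2, 2.55 without replicate 3 and 4.47 with that filter. Of 5 dendritic-cell markers 1 rose, 1 fell and 3 were not called (median 0.42, adjusted p = 0.636). Of 5 megakaryocyte markers 1 rose and 4 were not called (median 0.64, adjusted p = 0.71; 0 rose when adjusted over the list alone). The NK-cell list had 2 tested members, Gzma and Ccl5, both called higher, with at most 7.90 TPM and no read in the controls. The basophil list had 3, none called (median 0.80, or 0.68 with the bound); both were too small for a list test.

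**Figure D2:**
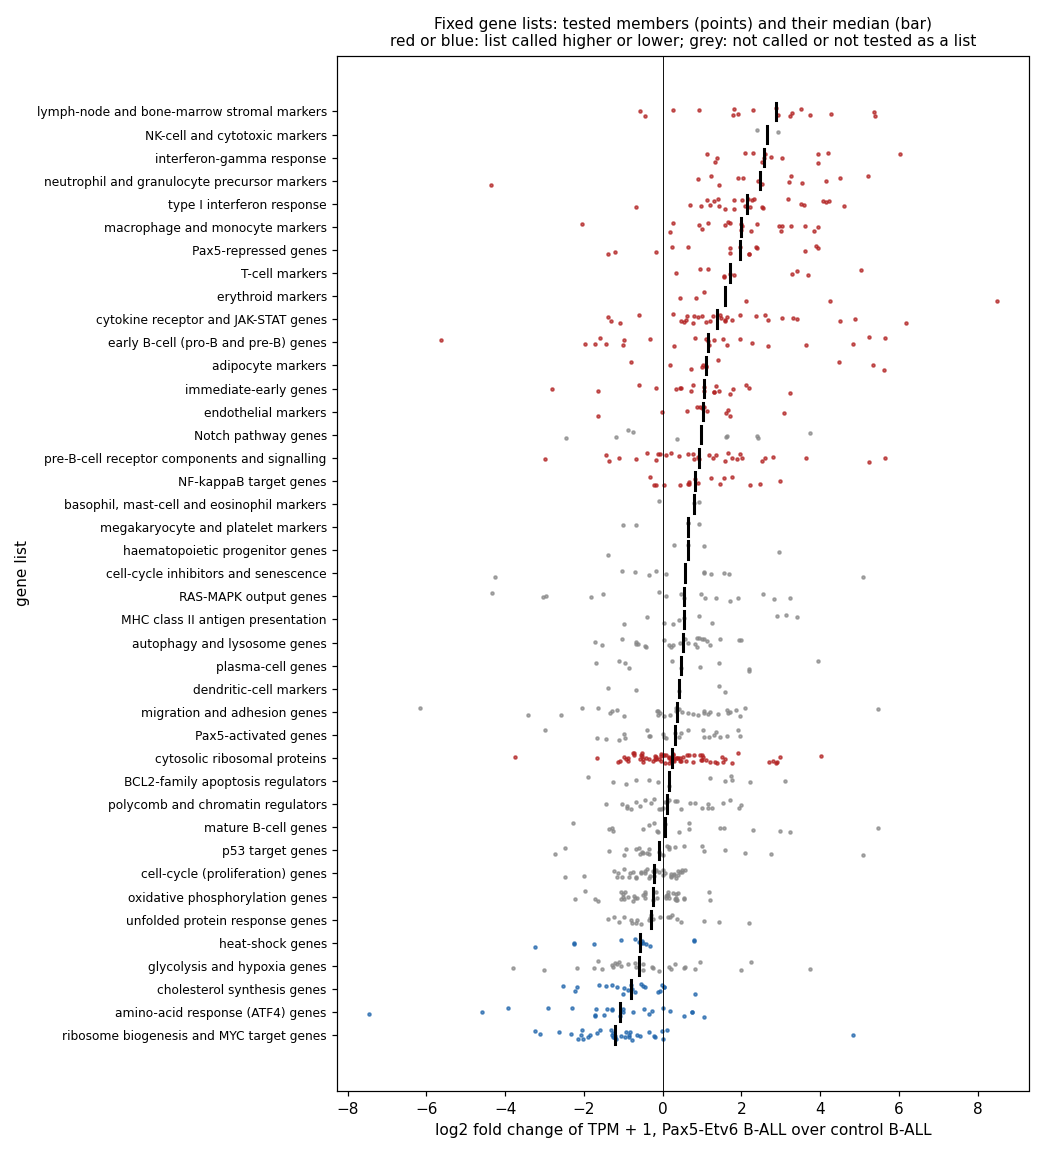
Log2 fold change of TPM + 1, Pax5-Etv6 over control B-ALL, on the horizontal axis for each tested member of the 41 gene lists, with a point per gene and a bar at each list's median. Red lists (16) were called higher and blue lists (4) lower by camera with a preset correlation.

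**Figure D3:**
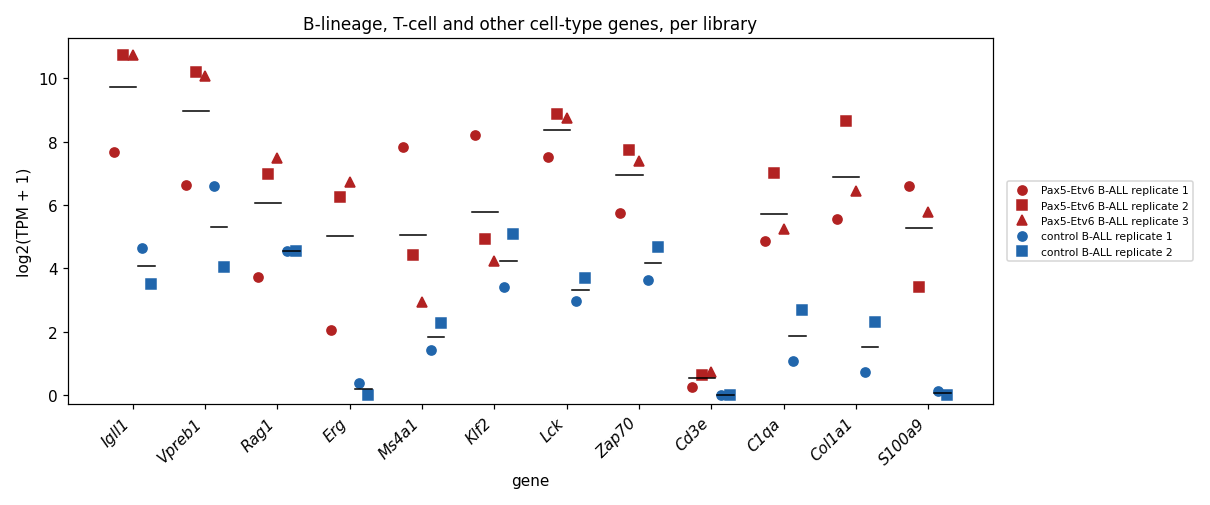
Expression of 12 lineage genes as log2(TPM + 1) on the vertical axis, with a point for each library and a bar at each group's mean (3 Pax5-Etv6 and 2 control libraries). Igll1, Erg and Rag1 were lowest and Ms4a1 and Klf2 highest in replicate 1 of the Pax5-Etv6 libraries, and Cd3e stayed under 1 TPM in all of them.

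The single genes with the largest differences were mostly outside these lists. Myl10, a myosin light chain, stood at 934 ± 612 against 0.139 ± 0.197 TPM (9.37 ± 0.69, adjusted p = 0.000507). Car2 followed, then an unnamed transcript listed as IMP_IDC_134 (7.71 ± 0.67, adjusted p = 0.000643) and Ccdc135 (7.49 ± 0.44, adjusted p = 0.000391). The further genes among the 12 largest rises were Eps8l2, Ston1, Mmp14, Syndig1l, Cnn2, Cish, Lgals3bp and Gfra2, with log2 fold changes from 6.81 down to 6.04. The neuronal ubiquitin hydrolase Uchl1 stood at 0.357 ± 0.386 against 387 ± 92.0 TPM (-8.17 ± 0.32, adjusted p = 0.00037). Asns and Cd44 came next, and the Wnt receptor Fzd9 stood at 0.0757 ± 0.0898 against 71.6 ± 32.3 TPM (-6.00 ± 0.35, adjusted p = 0.000391). Camkv, Insm1, Smyd2, Lalba, Enpep, Reln, Dnph1 and Kcnk1 completed the 12 largest falls, with log2 fold changes between -6.01 and -5.46. The names of Eps8l2 and Uchl1 carry an overlap tag.

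Across lists, camera with a preset correlation called 16 of 39 testable lists higher and 4 lower, none of these calls held with an estimated correlation, and fry called 6 higher and 4 lower. Of the 20 camera calls, fry kept the pre-B-cell receptor, cytokine, interferon-gamma, T-cell, erythroid, ribosome biogenesis, ATF4 and heat-shock lists. It did not call the type I interferon and Pax5-repressed (both 0.0514), neutrophil (0.0634), NF-kappaB (0.0641), adipocyte (0.07), macrophage (0.0849), early B-cell (0.139), cholesterol (0.166), immediate-early (0.171), ribosomal protein (0.186), stromal (0.194) and endothelial (0.214) lists. With 3 libraries against 2, a two-sided exact rank test cannot go below p = 0.2, so the calls rest on the variance model that limma shares across genes.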

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

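The fit on recovered reads and the fit without tagged genes were chosen after the results were seen. No called gene turned direction under any setting run. Over the settings that kept all 5 libraries the genes higher numbered 2182 to 3070 and the genes lower 3045 to 3509. Leaving out 1 library gave 1410 to 2984 genes higher and 1954 to 3350 lower, with the lowest counts in both directions without control B-ALL replicate 1, where the lone control is assumed to vary like the other group; 1391 of the 1410 and 1901 of the 1954 were also called with all libraries. Lists higher numbered 13 to 16 and lists lower 3 to 6 when a library was left out. With an estimated correlation camera called 0 lists higher and 0 lower (1 list at an unadjusted p under 0.05); it also tests on fewer degrees of freedom, and the cause was not tested. Fry called 6 lists higher. Without tagged genes 2 lists were lower, and the cause was not tested. Median-of-ratios scaling moved the median log2 fold change of all genes by 0.10 from -0.11, no filter also by 0.10, and voom on recovered reads by 0.11, so list medians near 0 are relative to that shift. Of 154 called genes checked one by one, 114 kept their call in every setting that tested them, 25 lost it only when a library was left out and 15 in both kinds of setting. Of 20 called lists, 12 kept their call in every setting with the preset correlation: pre-B-cell receptor, cytokine and JAK-STAT, both interferon lists, NF-kappaB, ribosome biogenesis, ATF4, T-cell, macrophage, neutrophil, erythroid and stromal. Lists not called that passed in at least 1 setting with the preset correlation were MHC class II (lowest adjusted p = 0.0216), cell cycle (0.036), glycolysis (0.0376), mature B-cell (0.0481) and autophagy (0.0496); with fry, cell-cycle inhibitors (0.03) and oxidative phosphorylation (0.037) passed.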

Other observations

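All tests weighed here were chosen after the result was seen, except the test of overlap-tagged genes, which was set before. Each Pax5-Etv6 library was dominated by 1 immunoglobulin heavy-chain V segment, and a different one in each. Ighv2-2 took 95.2% of the heavy-chain V reads of replicate 1 (95% Wilson interval 94.8 to 95.6), Ighv3-8 took 95.3% of those of replicate 2 (94.8 to 95.7) and Ighv5-6 took 96.5% of those of replicate 3 (96.2 to 96.8), over segments seen in at least 2 libraries. In the controls the leading segments took 45.7% (Ighv3-1, replicate 1, 44.8 to 46.7) and 50.2% (Ighv5-17, replicate 2, 49.2 to 51.2). The leading kappa segments were Igkv4-55 with 2726 TPM in Pax5-Etv6 replicate 1, next to Igkv2-137 with 1885 TPM, Igkv3-9 with 1377 TPM in replicate 2 and Igkv3-12 with 577 TPM in replicate 3. In the controls they were Igkv19-93 with 2022 TPM and Igkv3-2 with 1043 TPM. V segments are similar in sequence, so the counting could assign some reads to a neighbour of the true segment.

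Interferon genes varied between the Pax5-Etv6 libraries by class: members of the type I list were lowest in replicate 2 in 24 of 26 cases, and those of the interferon-gamma list were highest in replicate 3 in 14 of 14. Cytosolic ribosomal protein genes were highest in replicate 1 in 63 of 76 cases and lowest in replicate 3 in 67. Xist, the transcript of the inactive X chromosome, whose name carries an overlap tag, had 25.2 TPM in Pax5-Etv6 replicate 1 and at most 0.201 TPM elsewhere, and the Y-linked Ddx3y had 0.398 TPM there against 15.5 TPM or more in the others. Besides Asns, 12 tested genes had no read in all 3 Pax5-Etv6 libraries and at least 5 TPM in both controls, among them Umod (at least 82.7-fold lower). The 12 include the small RNAs Snord93 and Mir18, which had too few recovered reads for a fold change to be given. The reverse held for 4: Tox (at least 147-fold higher), Nlrx1, Dnajc6 and Crhbp. These genes were chosen after their values were seen. Genes with an overlap tag had a median log2 fold change of -0.04 (n = 1758) and untagged genes -0.11 (n = 9929). The difference was 0.07 (95% bootstrap interval 0.02 to 0.16), so tagged genes as a set showed no shift above 0.2. The labels do not say whether the control libraries were strand-specific, and a median cannot exclude a strand effect on single tagged genes.

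Markers of other cell types were higher in the Pax5-Etv6 libraries, which came from whole lymph node with no sort or gate. T cells as the source of Lck and Zap70 are argued against by the CD3 chains, whose sum was at most 0.572% of Lck and at most 1.97% of Zap70 in any Pax5-Etv6 library; expression in the leukaemic cells may be the source and was not tested. For macrophages, granulocytes and stromal cells the test could not decide. Members peaked together in 1 library in 18 of 21 macrophage, 11 of 14 neutrophil and 17 of 17 stromal markers (replicates 2, 1 and 2). At most 0.83% of 10000 random lists of like size and expression did so. Random lists hold unrelated genes, so any genes regulated together would also pass. Members of the interferon-gamma list, for example, were highest in replicate 3 in 14 of 14 cases. Such cells in shares that differ between libraries and shared regulation in the leukaemic cells thus cannot be told apart. The most abundant genes of the macrophage, neutrophil and stromal lists were Apoe (536 TPM in replicate 2), S100a9 (96.9 TPM in replicate 1) and Col1a1 (405 TPM in replicate 2). In these lists 9, 1 and 6 members reached 5 TPM in a control library, so part of the macrophage and stromal lists is also expressed without lymph node. The 1 neutrophil member was Gfi1, which fell, so no neutrophil marker that rose reached that level in a control library.

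Ribosome biogenesis and MYC target genes and genes of the ATF4 response were lower in the Pax5-Etv6 libraries. A lower share of leukaemic cells would lower B-lineage genes too. The 25 Pax5-activated genes had a median log2 fold change of 0.30 (95% interval -0.36 to 1.05), above the list medians of -1.21 and -1.08. Taken alone, this cannot decide the question, because the groups differ in a Pax5 allele and these genes may differ per cell. Within the list 9 rose and 5 fell, from 1.96 for Vpreb3 to -2.99 for Blnk. A lower share would, however, lower all genes of the leukaemic cells alike. Pax5 itself stood at 220 and 226 TPM. Of 32 pre-B-cell receptor genes 19 rose and 3 fell (median 0.92), and the 40 proliferation genes had a median of -0.23. These values argue against a lower share of leukaemic cells as the whole source of the 2 falls. A smaller part stays open, since markers of other cell types were higher. Scaling is argued against, since under 3 other scalings the list median closest to 0 was -0.97 and the highest camera adjusted p 0.00107. The retroviral Myc, the short culture, the tissue and the genotype all follow the groups and stay open, as untested; a candidate explanation is the difference in Myc, which the design could not separate from the others.

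Mature B-cell genes were higher in Pax5-Etv6 replicate 1 than in replicates 2 and 3: 11 of 17 listed genes were at least 2-fold above both, such as Ms4a1 (225 against 20.6 and 6.60 TPM) and Klf2 (293 against 29.3 and 17.9 TPM). The 17 leave out the tested immunoglobulin genes of the list, which were both highest in replicate 3. In replicates 1, 2 and 3 these were IGHD at 24, 23.8 and 37 TPM and IGHM at 6223, 4569 and 6290 TPM. Normal mature B cells in replicate 1 would bring other V segments. Heavy-chain segments other than the leading one rose by 57.5 TPM over the higher of the other libraries, less than the 205 TPM by which Ms4a1 rose, but the same measure for kappa segments stood at 2088 TPM against 159 and 215 TPM, of which Igkv2-137 made up 1885 TPM. An earlier form of the test had compared ratios, 1.53 for the heavy-chain segments and at least 2.18 for the genes. The ratio of V segments to Ms4a1 in normal mature B cells was not measured here, so such cells and a leukaemia at a later stage of B-cell maturation cannot be told apart as the source, and sex of the animal and dissection were not tested.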
